A study of Mus musculus with 12 samples.

How the data were processed

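Total RNA of 12 Min6 cultures, 4 per culture condition, had been hybridised to Affymetrix Mouse Gene 1.0 ST arrays after biotin labelling of cDNA, per the labels' protocols. The table used here holds the authors' deposited log2 expression value of each of 35556 probe sets on each array, with 1 value per probe set and array. The software that summarised the probes and any normalization between arrays are not given in the sources used here. That the values are log2 was read from their range, 3.69 to 14.5. The array medians range from 7.92 to 8.05, so the columns do not share a common distribution, and no further normalization was applied for the main results. Detection calls, scan dates and batches were not used here, so no value could be set against its background, and the number of arrays limits the precision. Culture condition and replicate number were taken from the sample titles.

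Probe sets were named through the platform annotation table supplied for the array. Of the 35556 rows, 21789 carry 1 gene symbol, 1621 several and 12146 none in that table. Of those with 1 symbol, 21698 were matched by gene identifier to a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. The authors' genome build is not given in the sources used here, so no coordinates are reported. All rows were tested, and genes were named only from rows with 1 symbol, which cover 19938 genes, 999 of them with more than 1 row. There are 6617 unnamed rows numbered before the first named row, a block that is not marked in the table. A total of 701 rows repeat the 12 values of another row, so counts of rows exceed counts of independent measurements. Some list members are not reported here. Where a gene had several rows, list tests used the row with the highest mean over all arrays.

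A linear model with 1 mean per condition was fitted to all 12 arrays with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3, leaving 9 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all 35556 rows of each comparison with a threshold of 0.05. Tests are two-sided. Errors of differences are limma's moderated standard errors, and errors of levels are SDs over 4 arrays. A list of 21 gene lists (beta cell identity, other islet hormones, exocrine and ductal markers, progenitor markers, Hes, Hey and Notch, JAK-STAT and Tie2, hypoxia, cholesterol, fatty acids, cell cycle, endoplasmic reticulum chaperones, ATF4, serum response, neuronal, interferon, antioxidant, iron, epithelial and mesenchymal, genes normally kept low in beta cells, markers of fibroblasts, endothelium and immune cells, and the respiratory chain) was fixed before the data were examined, together with the tests, the alternatives and the rule for naming genes. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 21 lists, and again with an estimated correlation and with fry. Of the camera calls, 1 of 8 held with the estimated correlation for DC against CC (cholesterol), 2 of 7 for RC against DC (cholesterol and fatty acids) and 0 of 3 for RC against CC. Lists without a camera call whose median, mean and test differed in sign were those of other islet hormones, progenitor markers, JAK-STAT and Tie2 and neuronal genes for DC against CC and RC against DC, of antioxidant genes for DC against CC, of serum response genes and genes kept low in beta cells for RC against DC, and of neuronal genes and iron handling for RC against CC. Fry, which asks whether a list's genes move on balance in a common direction, called 7, 6 and 0 lists.

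The rule for naming genes always gives Hes3, Ins1 (not analysed here) and Ins2, and in each comparison the 8 highest rises and 8 largest falls among called rows with 1 symbol whose groups do not overlap and whose higher group mean exceeds the median of all values, 1 row per gene and without predicted, clone-named, microRNA, small nucleolar or olfactory receptor genes, and for each list up to 4 called members with the largest change, or the 2 with the smallest p where none was called. Other list members are named where a count is small or a list is described, and those were chosen after their values were seen.

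A row that differed between DC and CC was classed as returned when it differed between RC and DC in the opposite direction but not between RC and CC, as partly returned when it also differed between RC and CC in the DC direction, as kept when it differed between RC and CC in the DC direction but not between RC and DC, and otherwise as other. For the share of the DC difference left in RC, 200 rows were chosen on 2 arrays per condition and measured on the remaining 2, over all 6 choices. For the shared CC arrays, correlation and covariance were set against 100 simulations of unchanged groups, and counts of shared rows against the overlap of independent lists. Both were also taken from fits with 2 CC arrays per comparison over 6 choices, with different CC arrays in the comparisons or, a test chosen after seeing the data, the same ones.

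The scripts were tested on simulated data with the row means and SDs of these arrays, with 35556 rows of which a known set was changed. For DC against CC, 92% of rows changed by 1 and 57% of rows changed by 0.5 on the log2 scale were recovered, and 3 of 35327 unchanged rows were called. For RC against DC these shares were 94% and 54% with 5 unchanged rows called, and for RC against CC 82% and 36% with 4. A list of raised genes ranked first by camera for DC against CC over 19938 genes, and 94% of returned and 82% of kept rows with a change of 1 were classed as such. The simulated values were independent between rows and arrays. They hold neither the correlation between genes nor the unequal spread of the real arrays, so these shares and false calls may differ in the real data.

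The alternatives were quantile normalization, centring on the median, brighter rows only, rows with 1 symbol only, eBayes with a trend and robust variances, array weights, fitting only the groups compared, the replicate number as a block, a 2-fold minimum, a test against 1.2-fold, and leaving out each array in turn; for lists also the mean of a gene's rows. Leaving out the 3 arrays of narrowest spread, the interquartile range as a covariate and leaving out the unnamed rows at the start of the numbering were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.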

Results

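Gene expression was measured in Min6 cells, a mouse insulinoma line that makes insulin and is widely used as a model of pancreatic beta cells, after 3 consecutive culture periods of 5 days each. Under classic conditions (CC) the cells stayed in medium with 15% serum at 20% oxygen throughout. Under defined conditions (DC) they spent the final 10 days without serum at 5% oxygen, in a medium supplemented with transferrin, progesterone, putrescine and selenite. Under the return condition (RC) they spent 5 days in the serum-free medium at 5% oxygen and the last 5 days back in serum at 20% oxygen. Each condition was represented by 4 arrays (12 in all) of the Affymetrix Mouse Gene 1.0 ST type, which gives 1 log2 expression value for each of 35556 probe sets, called rows here. The series concerns culture conditions that alter the expression and localization of Hes3, a transcriptional repressor of the Hes and Hey family. The comparisons ask which genes differ between the conditions and which of those differences are also seen after the return. Serum, oxygen and these supplements changed together, so every difference belongs to the combination. DC arrays had 10 serum-free days and RC arrays 5, and cultures at the end of those 5 days were not analysed here, so RC against DC holds the length of the exposure as well as the return. The quadruplicates came from a single experiment, and the p-values measure the spread between these samples.

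The 12 arrays had medians of 7.92 to 8.05 and interquartile ranges of 2.42 to 2.75 on the log2 scale. The CC arrays fell into pairs. Interquartile ranges were 2.73 and 2.75 on CC 1 and CC 2, and 2.58 and 2.57 on CC 3 and CC 4. Correlations were 0.996 and 0.998 within these pairs and 0.993 to 0.994 across them. Some genes named below differed between the pairs. Dusp6 read 10.14 and 10.20 against 9.48 and 9.61, and Id1 10.03 and 10.09 against 9.46 and 9.52. What set the pairs apart was not tested. Array RC 3 stood apart from the other RC arrays. Its mean correlation with them was 0.976, against 0.989 to 0.990 for the other 3, whose means include RC 3. Its interquartile range was the narrowest, followed by DC 4 (2.44) and DC 2 (2.47). The groups' interquartile ranges did not differ beyond chance (exact two-sided permutation tests, p = 0.171 for DC against CC, 0.686 for RC against DC and 0.286 for RC against CC; 0.0286 is the smallest p that 4 against 4 allows).

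**Figure D1:**
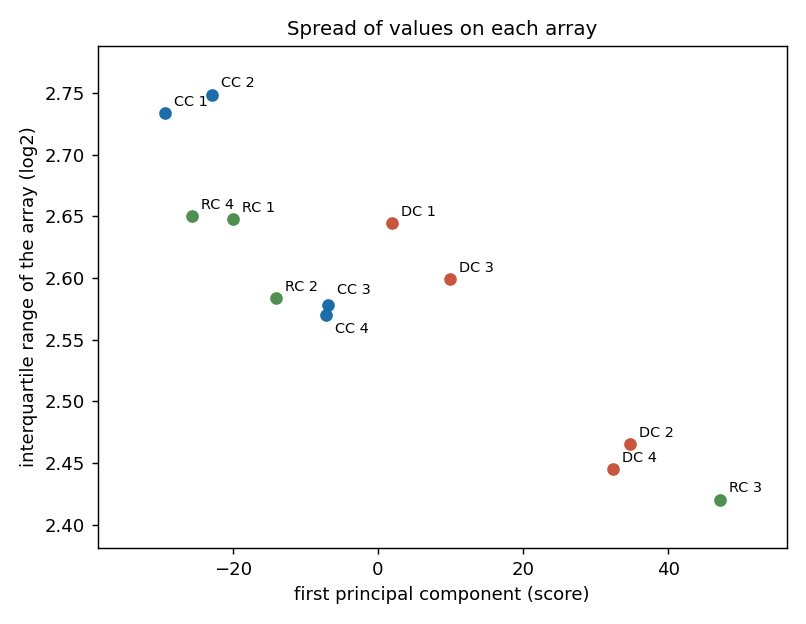
Interquartile range of the log2 values of each array (vertical axis) against its score on the first principal component of all rows (horizontal axis), with 1 point per array coloured by condition. RC 3 lies at a score of 47.1, away from the other RC arrays at -25.6 to -14.0, and the nearest arrays are DC 2 at 34.7 and DC 4 at 32.3.

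Hes3 itself did not pass the test in any comparison. Its probe set (10518902) read 7.27 ± 0.13 in CC, 7.36 ± 0.15 in DC and 7.38 ± 0.16 in RC (SD, n = 4), below the median of all values, 7.99. The 95% interval of its log2 difference ran from -0.12 to 0.31 for DC against CC, from -0.19 to 0.24 for RC against DC and from -0.10 to 0.33 for RC against CC. The insulin gene Ins2 (probe set 10569358) was near the top of the scale in all 3 conditions, at 13.03 ± 0.03 in CC, 13.05 ± 0.04 in DC and 13.02 ± 0.05 in RC, and did not pass either, with 95% intervals of -0.10 to 0.13, -0.14 to 0.08 and -0.13 to 0.09 in the same order. Ins1 was not analysed here.

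DC was compared with CC to find what 10 days without serum at low oxygen changed. Most measured genes of the hypoxia response and of cholesterol synthesis and part of those of fatty acid synthesis rose in DC, while Id1, Id2, Id3 and part of the serum response, endoplasmic reticulum chaperone and cell cycle genes fell. The highest rise among the named genes was that of Ak4, a mitochondrial adenylate kinase, by 2.74 ± 0.25 on the log2 scale (SE, n = 4 per group; 6.69-fold; limma adjusted p = 3.7e-05). It was followed by the mitophagy receptor Bnip3 (2.46 ± 0.20; 5.51-fold), the pyruvate dehydrogenase kinase Pdk1 (2.32 ± 0.23) and the glycolytic aldolase Aldoc (2.29 ± 0.15). Then came Prelid2 (2.19 ± 0.23), Mgarp (2.00 ± 0.29), the lactate dehydrogenase Ldha (1.98 ± 0.16) and the lactate transporter Slc16a3 (1.89 ± 0.20). Ak4 has a second probe set, which rose less (0.87). The named falls were headed by the secreted matrix protein gene Ccdc80 (-2.51 ± 0.12; 5.71-fold; adjusted p = 7.3e-07), Fgl2 (-2.07 ± 0.10), the ERK phosphatase Dusp6 (from 9.86 ± 0.36 in CC to 7.86 ± 0.27 in DC; SD, n = 4) and Fndc1 (-1.99 ± 0.21). They went on with the metalloprotease Tll1 (-1.96 ± 0.11), the neurokinin receptor Tacr3 (-1.91 ± 0.07), the opsin Opn5 (-1.82 ± 0.13) and Id2 (-1.77 ± 0.13).

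Over all rows, 2360 of 35556 differed between DC and CC (adjusted p under 0.05), 823 higher and 1537 lower in DC. Of these, 170 differed at least 2-fold, 65 higher and 105 lower. The 2360 rows covered 1833 genes with a row of their own, 600 higher, 1232 lower and 1 with rows in both directions. With the arrays centred on a common median the split was 502 higher and 1698 lower, and with the interquartile range as a covariate 1203 and 1253. The count was 3718 without RC 3, which is in neither group but enters the estimate of the spread, 1549 without DC 2, 1570 without CC 1 and 4840 with array weights.

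In the hypoxia response list, 22 of 29 measured members rose in DC, none fell and 7 did not pass (23 rose when adjusted over the list alone). Besides the genes above these included the glucose transporter Slc2a1 (1.18 ± 0.20), the regulatory glycolytic enzyme Pfkfb3 (1.87 ± 0.18) and Ndrg1 (1.39 ± 0.11). Car9 and Hk2, at 7.14 ± 0.10 and 7.29 ± 0.16 in DC against 6.98 ± 0.10 and 7.11 ± 0.07 in CC (SD, n = 4), did not pass. The median change was 0.94, and camera placed the list above other genes (adjusted p = 9.3e-20), with an adjusted p = 0.13 with an estimated correlation.

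Of 20 measured genes of cholesterol synthesis and uptake, 17 rose and 1 fell (18 and 1 adjusted over the list alone). Hmgcs1, which encodes an early enzyme of the pathway, rose by 1.70 ± 0.10 (3.26-fold; adjusted p = 1.8e-06), Idi1 by 1.29 ± 0.16, Lss by 1.28 ± 0.09 and Nsdhl by 1.19 ± 0.11. The exception was the sterol isomerase gene Ebp (-0.48 ± 0.10). The list passed camera with the preset correlation (adjusted p = 7.4e-19) and with an estimated one (adjusted p = 0.042). Of 16 genes of fatty acid synthesis and desaturation, 6 rose and none fell (10 rose adjusted over the list alone), among them the desaturase Scd1 (1.13 ± 0.12), Acss2 (1.06 ± 0.11) and the fatty acid synthase Fasn (0.92 ± 0.07). This list's adjusted p was 2.5e-05 with camera and the adjusted p = 0.071 with an estimated correlation.

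Of 20 endoplasmic reticulum chaperone and unfolded protein response genes, 10 fell and none rose (16 fell adjusted over the list alone). Dnajb11 fell by 0.96, Dnajc3 by 0.73, Creld2 by 0.50 and Pdia4 by 0.50, with a camera adjusted p = 3.3e-11 and an adjusted p = 0.31 with an estimated correlation. A second, dimmer probe set of Pdia4 did not pass (-0.16, limma adjusted p = 0.39). Of this list 6 fell without CC 1, without DC 2, and without the 3 arrays of narrowest spread (DC 2, DC 4 and RC 3). Among 31 cell cycle and DNA replication genes, 5 fell and none rose (17 fell adjusted over the list alone): Rrm2 (-0.95 ± 0.12), Ccnd2 (-0.86 ± 0.13), Tyms (-0.52 ± 0.09), Ccna2 (-0.45 ± 0.10) and Ccne1 (-0.35). The list's camera adjusted p was 3.3e-11, with an adjusted p = 0.45 with an estimated correlation, and 8 members fell without DC 4 or without RC 3. In the list of serum response and immediate early genes, 6 of 25 fell and 1 rose (7 and 1 adjusted over the list alone). Dusp6 and Spry4 (-0.73 ± 0.13), feedback inhibitors of ERK signalling, fell with the cytoskeletal genes Vcl (-0.57 ± 0.09) and Tpm1 (-0.55 ± 0.11), and Ier3 rose (0.48). Camera gave an adjusted p = 0.02 for this list and an adjusted p = 0.49 with an estimated correlation. In the mitochondrial respiratory chain list 1 of 21 members, Cyc1 (-0.34 ± 0.09), fell and none rose (2 fell adjusted over the list alone; camera adjusted p = 0.0084, and adjusted p = 0.80 with an estimated correlation). In the respiratory chain list 2 fell without CC 4 or RC 3. Some calls in these lists ended when a single array was left out: that of Creld2 without CC 1, CC 2, CC 3, CC 4, DC 2, DC 3, DC 4, RC 1 or RC 2 (adjusted p up to 0.117) and that of Cyc1 without each array except CC 4, DC 3 and RC 3 (up to 0.156). Ier3 did not pass without CC 1, CC 2, CC 3, CC 4, DC 1, DC 2 or DC 3 (up to 0.0917), Ccna2 without CC 1, CC 2 or DC 2 (up to 0.0699) and Pdia4 without CC 1 or DC 2 (up to 0.0591).

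Among 31 beta cell identity and insulin secretion genes, 5 rose and 2 fell (8 and 3 adjusted over the list alone), and camera did not call the list (adjusted p = 0.46). Without CC 1, CC 4 or DC 4, and without the 3 arrays of narrowest spread, 3 rose. The incretin receptor Gipr rose by 0.86 ± 0.08 (1.82-fold; adjusted p = 4.6e-05), the granule protein Sytl4 by 0.73 ± 0.08, the transcription factors Pax6 by 0.53 ± 0.05 and Nkx2-2 by 0.29, and the zinc transporter Slc30a8 by 0.31. Cltrn, a membrane protein of beta cells, fell by 1.19 ± 0.16, and the granin Chgb fell by 0.29. Slc30a8 did not pass without CC 1, CC 2, CC 3, CC 4, DC 2, DC 3, DC 4, RC 1 or RC 2 (adjusted p up to 0.133), Nkx2-2 without CC 1, CC 4 or DC 4 (up to 0.0703), and Chgb without CC 4 or DC 2 (up to 0.0541). Pdx1, Mafa and Nkx6-1 did not pass. Of 12 genes of other islet hormones and their regulators, 3 fell and none rose (3 adjusted over the list alone), namely the somatostatin gene Sst (-1.26 ± 0.24), Ttr (-0.55 ± 0.09) and Cck (-0.40 ± 0.06).

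In the list of progenitor and dedifferentiation markers, 4 of 18 fell and 1 rose (5 and 1 adjusted over the list alone). Id1 (-1.42 ± 0.14), Id2 and Id3 (-0.88 ± 0.13), inhibitors of basic helix-loop-helix factors, fell with Cd44, and Prom1 rose (0.43 ± 0.11). With single arrays left out in turn, Prom1 passed only without RC 2, RC 3 or RC 4 (adjusted p up to 0.121 otherwise) and Cd44 only without DC 1 or RC 3 (up to 0.155). Among 22 Hes, Hey and Notch pathway genes, 1 passed, the ligand gene Dll1, which rose by 0.43 ± 0.08 (1 adjusted over the list alone). In the JAK-STAT and Tie2 signalling list 5 of 21 fell and 1 rose (6 and 1 adjusted over the list alone). The Tie2 ligand Angpt2 was at -1.17 ± 0.13, the receptor genes Igf1r at -0.65 ± 0.14 and Lifr at -0.57 ± 0.10, the cytokine-inducible Cish at -0.48 ± 0.06 and Stat5a at 0.32, which did not pass without CC 2 or DC 2 (adjusted p up to 0.053), and 2 rose without RC 3. Of 20 antioxidant, metallothionein and selenoprotein genes, 3 rose and 3 fell (5 and 3 adjusted over the list alone). The metallothioneins Mt1 (1.12 ± 0.06; adjusted p = 9.7e-07) and Mt2 (1.01 ± 0.07) rose, and Txnip, an inhibitor of thioredoxin, fell (-1.61 ± 0.12), as did the selenium carrier Selenop (-0.70 ± 0.10). Of 11 iron handling genes 3 fell and none rose (3 adjusted over the list alone), among them the iron exporter Slc40a1 (-1.37 ± 0.09) and the importer Slc11a2 (-0.42 ± 0.08).

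In the epithelial and mesenchymal list 2 of 21 rose and 3 fell (2 and 3 adjusted over the list alone), with Tgfb2 at 0.74 ± 0.11 and Lamc1 at -0.70 ± 0.09. In the interferon and inflammatory list 2 of 19 rose and 2 fell (4 and 2 adjusted over the list alone), with 0 falls without CC 1, CC 2, DC 2 or DC 3 and 1 rise without CC 2, CC 3 or CC 4, and in the neuronal list 1 of 15 rose, Map2, and 1 fell, Dcx (2 and 2). In the ATF4 and amino acid response list 1 of 21 rose, Ddit3, and 1 fell, the collagen receptor gene Ddr2 (2 and 1), and 3 rose without DC 4. With single arrays left out in turn, Ddit3 passed only without DC 4 or RC 3 (adjusted p up to 0.139 otherwise). In the list of genes normally kept low in beta cells 1 of 16 rose, Ldha, and 1 fell, Igfbp4 (1 and 1). No member passed among 15 exocrine and ductal markers or among 14 fibroblast, endothelial and immune markers (0 adjusted over the list alone in both). Camera placed the latter list above other genes (adjusted p = 0.04, and adjusted p = 0.80 with an estimated correlation). Without DC 4, 1 member of that list rose. With expression levels divided into 5 classes from low to high, the median changes in DC were 0.046, 0.111, 0.099, -0.025 and -0.055. Camera takes no account of this trend with level, and its share in the list calls was not tested. In the ATF4 list 2 fell without DC 3 and 2 rose without RC 3, and in the neuronal list 2 fell when either of these arrays was left out. Other splits of these 8 arrays gave up to 11 list calls by camera and 0 called rows.

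**Figure D2:**
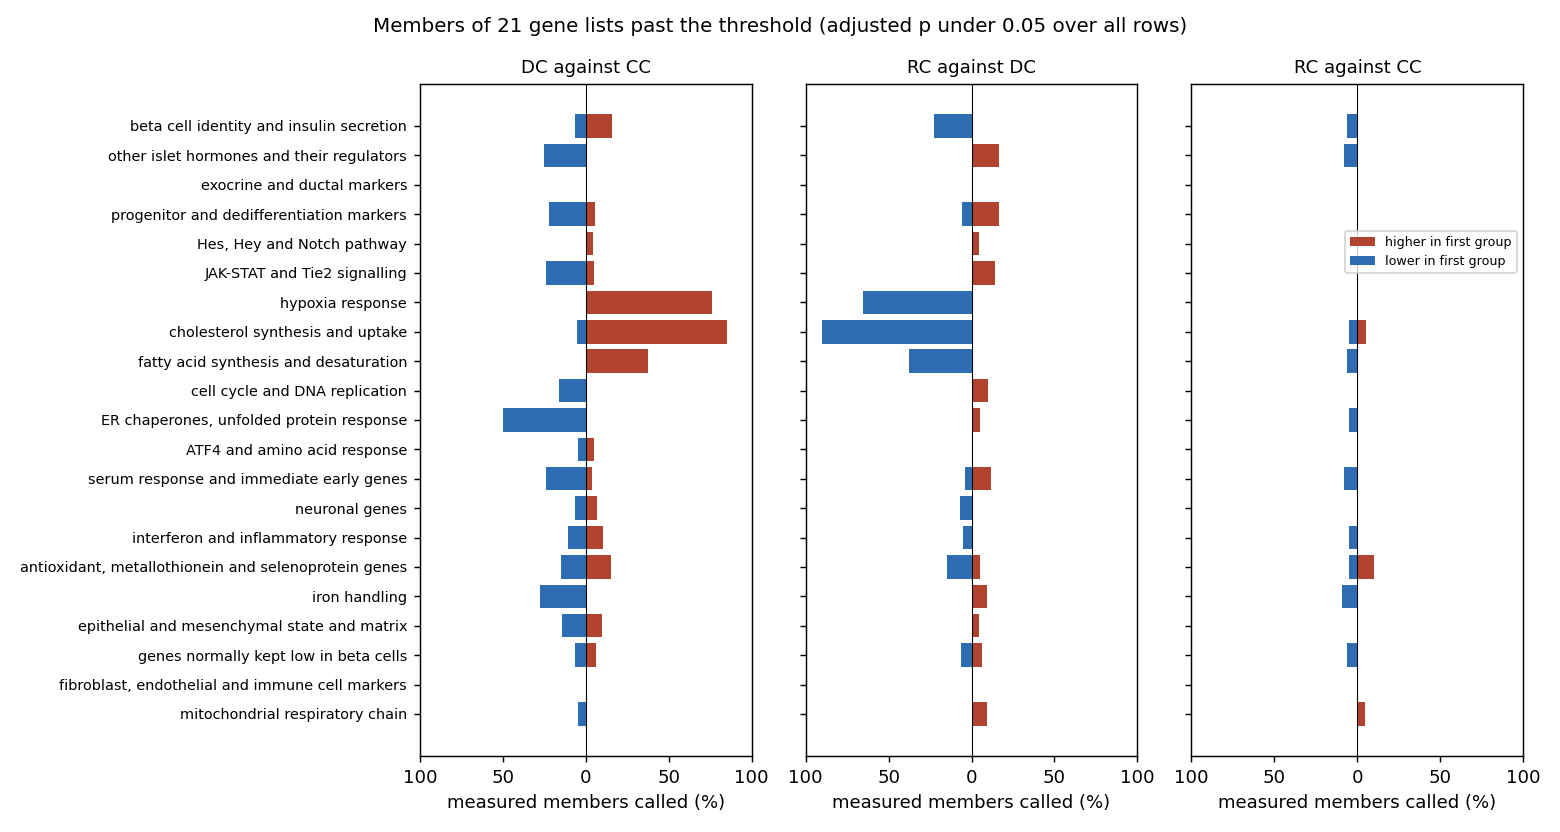
Share of the measured members of each of the 21 gene lists that passed the test in each comparison (horizontal axis, percent; bars to the right are higher and bars to the left lower in the condition named first). The hypoxia list had 22 of 29 members higher in DC than in CC and 19 of 29 lower in RC than in DC, and the cholesterol list 17 and 18 of 20.

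RC was compared with DC to find how cells with 5 serum-free days and 5 days back in serum at 20% oxygen differed from cells with 10 serum-free days. Most hypoxia and cholesterol genes and part of the fatty acid genes were lower in RC, and Id1, Id2, Id3, Dusp6 and Sst were higher. The largest falls among the named genes were those of Slc16a3 (-1.84 ± 0.20 on the log2 scale; SE, n = 4 per group; 3.59-fold; adjusted p = 0.00033), Aldoc (-1.80 ± 0.15), Ak4 (-1.80 ± 0.25) and Mgarp (-1.77 ± 0.29). Next were Bnip3 (-1.52 ± 0.20), Ldha (-1.48 ± 0.16), Pdk1 (-1.43 ± 0.23) and Pfkfb3 (-1.42 ± 0.18). The highest rises were those of Opn5 (1.93 ± 0.13; 3.82-fold; adjusted p = 1.4e-05), Id2 (1.88 ± 0.13), Ccdc80 (1.87 ± 0.12) and the steroid dehydrogenase Akr1c18 (1.79 ± 0.19). Next were the calcium buffer Calb1 (1.79 ± 0.13), Fgl2 (1.78 ± 0.10), the cytokine signalling inhibitor Socs2 (1.75 ± 0.17) and Sst (1.70 ± 0.24). Socs2 has another probe set, which rose by 0.46 ± 0.06.

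In total 936 rows differed, 516 higher and 420 lower in RC, of which 76 differed at least 2-fold (45 higher and 31 lower). The 936 rows covered 743 genes, 398 higher and 345 lower. This count rests on the arrays used: 2892 rows passed without RC 3, and a split that set RC 3 with DC 2, DC 3 and DC 4 against the other 4 arrays gave 7241. So does the direction, with 1981 higher and 911 lower without RC 3, 403 higher and 458 lower without DC 4, and 616 and 619 with quantile normalization. The count was 522 without RC 1, 578 without RC 2, 574 without RC 4 and 578 without DC 2, 462 with only these groups in the fit and 6413 with array weights.

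Of the 29 hypoxia genes 19 fell and none rose (24 fell adjusted over the list alone; camera adjusted p = 1.6e-28, and adjusted p = 0.052 with an estimated correlation). Of the 20 cholesterol genes 18 fell and none rose (19 adjusted over the list alone), including Hmgcs1 (-1.09 ± 0.10), Tm7sf2 (-1.04 ± 0.11), Nsdhl (-0.99 ± 0.11) and Lss (-0.95 ± 0.09). Of the 16 fatty acid genes 6 fell and none rose (10 adjusted over the list alone), with Acss2 at -0.98 ± 0.11, Scd1 at -0.97 ± 0.12 and the regulator Srebf1 at -0.73 ± 0.06. Both lists passed camera (adjusted p = 6.6e-33 and 3.3e-12) and kept their call with an estimated correlation (adjusted p = 0.0037 for both). Of 31 beta cell genes 7 fell and none rose (10 fell and 1 rose adjusted over the list alone; camera adjusted p = 2.1e-06, and adjusted p = 0.31 with an estimated correlation). They were Gipr (-0.95 ± 0.08), Sytl4 (-0.83 ± 0.08), Slc30a8 (-0.45 ± 0.08), Trpm5 (-0.37 ± 0.09), Pax6, Nkx2-2 and Ptprn2. Without DC 2, DC 4 and RC 3 the falls in this list numbered 3, and without RC 1 alone 4, and 1 member rose without RC 3. With single arrays left out in turn, Trpm5 passed only without CC 2, DC 1 or RC 3 (adjusted p up to 0.166 otherwise). Ptprn2 did not pass without CC 3, CC 4, DC 2, DC 3, DC 4, RC 1 or RC 2 (up to 0.0957), and Nkx2-2 without RC 1 or RC 4 (up to 0.0655). Of 31 cell cycle genes 3 rose and none fell (10 rose adjusted over the list alone; camera adjusted p = 1.5e-12, and adjusted p = 0.33 with an estimated correlation), Rrm2 by 0.75 ± 0.12, Ccnd2 by 0.66 ± 0.13 and Cdk1 by 0.49 ± 0.11. The rises in the cell cycle list numbered 8 without RC 3, 7 without DC 4, 1 without RC 1 or RC 4, and 6 without DC 2, DC 4 and RC 3. The Cdk1 call ended without DC 2, DC 3, RC 1, RC 2 or RC 4 (adjusted p up to 0.112) and that of Ccnd2 without RC 1 or RC 4 (up to 0.0591). In the respiratory chain list Ndufa4 rose by 0.83 ± 0.13 and the coactivator Ppargc1a by 0.68 ± 0.08, and the other 19 of 21 did not pass (2 rose adjusted over the list alone; camera adjusted p = 3.5e-08, and adjusted p = 0.33 with an estimated correlation). In the chaperone list 1 of 20, Dnajb11 (0.79 ± 0.15), rose (2 adjusted over the list alone; camera adjusted p = 0.0019, and adjusted p = 0.65 with an estimated correlation), and 4 rose without DC 1, 2 rose without RC 3 and 1 fell without DC 4, while Dnajb11 itself did not pass without RC 1 (adjusted p = 0.054).

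Camera did not call the remaining lists in this comparison. In the progenitor list Id1 (1.45 ± 0.14), Id2 and Id3 (1.06 ± 0.13) rose and Prom1 fell (-0.73 ± 0.11), with 4 rises and 1 fall adjusted over the list alone. In the serum response list Dusp6 (1.58 ± 0.17), Tpm1 (0.66 ± 0.11) and Spry4 (0.60 ± 0.13) rose and Ier3 fell (6 and 1 adjusted over the list alone). In the JAK-STAT and Tie2 list Angpt2 (adjusted p = 0.00035), Socs2 and Cish (0.44 ± 0.06) rose and none fell (6 rose and 2 fell adjusted over the list alone). Hey1 rose (0.64 ± 0.15; adjusted p = 0.043) in the Hes, Hey and Notch list (2 rose adjusted over the list alone) and Slc40a1 (0.90 ± 0.09) in the iron list (2). Sst rose with Cck (0.40 ± 0.06) among the other islet hormones (2), and Lamc1 (0.53 ± 0.09) in the epithelial and mesenchymal list (2, with 2 falls). In the antioxidant list Txnip rose by 1.23 ± 0.12, whereas Mt1 (-0.51 ± 0.06), Mt2 (-0.46 ± 0.07) and Nqo1 (-0.62 ± 0.14) fell (2 rose and 3 fell adjusted over the list alone). Tnfaip3 fell (-0.38 ± 0.09) in the interferon list (2 fell adjusted over the list alone) and Syt1 (-0.35 ± 0.08) in the neuronal list (2 rose and 2 fell). Among the genes normally kept low in beta cells Ldha fell and Igfbp4 rose (0.50 ± 0.08; 1 and 1 adjusted over the list alone). No member passed in the exocrine and ductal, the fibroblast, endothelial and immune or the ATF4 list (0 adjusted over the list alone in each). Without DC 4, 2 members of the ATF4 list fell, and without RC 3 the rises numbered 5 in the JAK-STAT and Tie2, 3 in the antioxidant, 2 in the neuronal and 2 in the iron list (2 also without DC 3). The falls numbered 1 each without RC 3 in the Hes, Hey and Notch, JAK-STAT and Tie2, ATF4 and epithelial and mesenchymal lists (1 in the last also without DC 4). They numbered 2 in the interferon list without RC 3 and 2 in the serum response list without DC 4. Several calls near the threshold ended when a single array was left out. Hey1 did not pass without CC 2, CC 3, DC 2, DC 4, RC 1, RC 2 or RC 4 (adjusted p up to 0.15). For Spry4 and Nqo1 these arrays were DC 2, DC 3, DC 4, RC 1, RC 2 and RC 4 (up to 0.0875 and 0.126), and for Ier3 all but DC 4 and RC 3 (up to 0.166). They were CC 1, CC 3, CC 4, DC 2, DC 3, RC 1, RC 2 and RC 4 for Tnfaip3 (up to 0.141), and the same with CC 2 for Syt1 (up to 0.145).

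**Figure D3:**
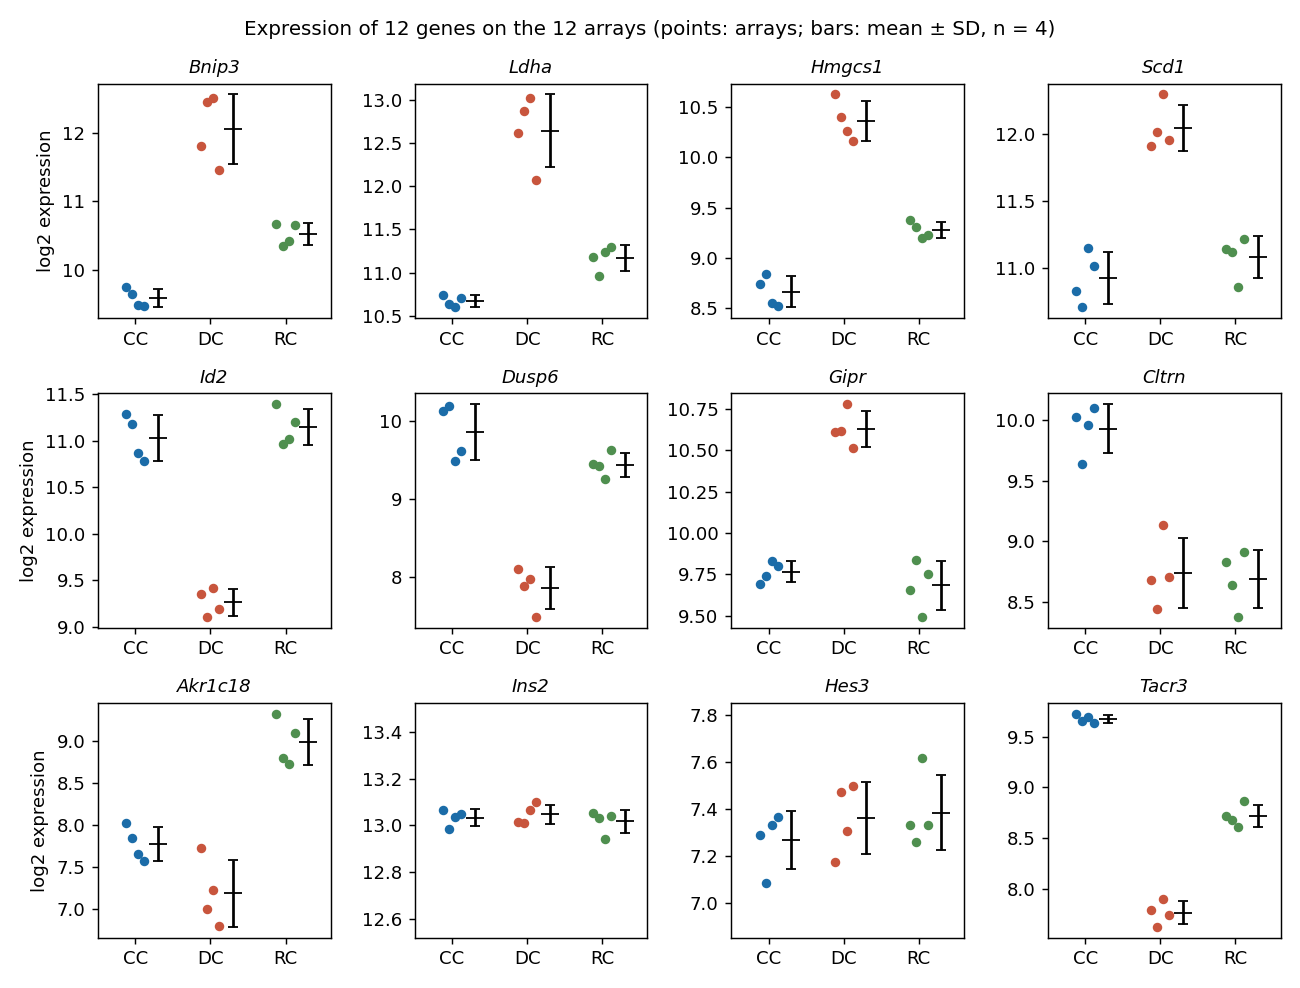
Log2 expression (vertical axes) of 12 genes on each array, grouped by condition (CC, DC and RC); points are arrays, and the bar beside them gives the mean and SD (n = 4). Bnip3 was at 9.59 in CC, 12.05 in DC and 10.53 in RC, Cltrn at 9.93, 8.74 and 8.69, and Hes3 at 7.27, 7.36 and 7.38.

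RC was compared with CC to find what differed after the return. The rises were small in number and included the steroid dehydrogenase Akr1c18, both metallothioneins and Hmgcs1, and the falls included the xenobiotic epoxide hydrolase Ephx1, Cltrn, the angiotensinogen gene Agt and the caveolin Cav1. Akr1c18 was higher by 1.21 ± 0.19 on the log2 scale (SE, n = 4 per group; 2.31-fold; adjusted p = 0.015), the opsin Opn3 by 0.82 ± 0.14, the synaptic vesicle protein gene Sv2b by 0.72 ± 0.08, and Cpeb1 by 0.67 ± 0.12. Next were the glutamate transporter Slc1a2 (0.62 ± 0.06), Mt1 (0.62 ± 0.06), Hmgcs1 (0.62 ± 0.10) and Ppargc1a (0.59 ± 0.08). The largest falls were those of Ephx1 (-1.25 ± 0.12; 2.37-fold; adjusted p = 0.00049), Cltrn (-1.24 ± 0.16), Fam151a (-1.02 ± 0.13), Agt (12.93 ± 0.10 in CC and 11.93 ± 0.15 in RC; SD, n = 4), Cav1 (9.21 ± 0.06 and 8.21 ± 0.11), Tacr3 (-0.96 ± 0.07), Tm4sf4 (-0.96 ± 0.12) and Serping1 (-0.90 ± 0.18). The Akr1c18 call ended without CC 3, CC 4 or RC 1 (adjusted p up to 0.0661) and that of Hmgcs1 without CC 1, CC 3, CC 4, RC 1 or RC 2 (up to 0.0881). Opn3 and Cpeb1 did not pass without CC 1, CC 2, CC 3, CC 4, RC 1, RC 2 or RC 4 (up to 0.0878 and 0.11), and Serping1 passed only without DC 1, DC 3 or DC 4 of the single arrays (up to 0.157 otherwise).

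In total 283 rows differed, 43 higher and 240 lower in RC, and 6 of them at least 2-fold (1 higher and 5 lower). The 283 rows covered 250 genes, 33 higher and 217 lower. The share of higher rows was 15.2%. It was 41.2% among the 580 rows that passed without RC 3, DC 2 and DC 4, the arrays of narrowest spread, 42.8% with the interquartile range as a covariate and 52.4% of 2818 rows with array weights. The count was 91, 105, 64 and 64 without CC 1, CC 2, CC 3 and CC 4, and 57, 88 and 151 without RC 1, RC 2 and RC 4.

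No hypoxia gene passed between RC and CC over all rows (2 rose adjusted over the list alone). That count rests on the arrays used: 5 were higher in RC without DC 4 and 1 without DC 3, arrays in neither group, 4 were higher without DC 2, DC 4 and RC 3, and none was lower in these settings. Bnip3 read 10.53 ± 0.16 in RC against 9.59 ± 0.13 in CC (adjusted p = 0.053) and Pdk1 8.95 ± 0.11 against 8.07 ± 0.07 (adjusted p = 0.14), and without DC 4 both passed (adjusted p = 0.016 for each). A second, dimmer probe set of Bnip3 was higher in RC by 0.67 (limma adjusted p = 0.25). The list as a whole lay above other genes (median 0.14; camera adjusted p = 0.0028), with an adjusted p = 0.78 with an estimated correlation. Among the 20 chaperone genes Xbp1, a regulator of the unfolded protein response, fell (-0.40 ± 0.07) and 19 did not pass (7 fell adjusted over the list alone; camera adjusted p = 5.3e-11, and adjusted p = 0.78 with an estimated correlation). In the beta cell list Cltrn and Ptprn2 (-0.34 ± 0.06) fell and none rose (3 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00014, and adjusted p = 0.78 with an estimated correlation). In the antioxidant list Mt1 and Mt2 (0.55 ± 0.07) were higher and Selenop lower (-0.86 ± 0.10; 2 and 2 adjusted over the list alone), and in the cholesterol list Hmgcs1 was higher and Ebp lower (-0.53 ± 0.10; 3 and 1 adjusted over the list alone). Ppargc1a was the sole called member of the respiratory chain list (1 rose adjusted over the list alone). In the serum response list Jun (-0.53 ± 0.08) and Vcl (-0.48 ± 0.09) were lower (2 adjusted over the list alone). A single member each was lower in the fatty acid list (Srebf1, -0.30 ± 0.06; 1 rose and 2 fell adjusted over the list alone), the iron list (Slc40a1, -0.47 ± 0.09; 1 and 3) and the interferon list (Tap1, -0.43 ± 0.07; 1 and 1). The same held for the other islet hormones (Ttr, -0.47 ± 0.09; 0 and 1) and the genes normally kept low in beta cells (Igfbp4, -0.45 ± 0.08; 0 and 1). No member passed over all rows in the cell cycle, progenitor, JAK-STAT and Tie2, exocrine and ductal, and fibroblast, endothelial and immune lists (0 adjusted over the list alone in each). None passed either in the Hes, Hey and Notch list (1 fell adjusted over the list alone), the neuronal list (1 fell), the ATF4 list (3 fell) or the epithelial and mesenchymal list (1 rose and 1 fell). Without DC 4, 3 members of the ATF4 list and 3 of the chaperone list were lower in RC, and 2 of the cholesterol list, 1 of the epithelial and mesenchymal list and 1 of the genes normally kept low in beta cells were higher. Without DC 1, 2 members each of the chaperone and iron lists were lower, and without DC 3, 1 of the neuronal list. The calls of Xbp1, Ptprn2, Hmgcs1, Ebp, Vcl, Srebf1, Slc40a1, Tap1, Ttr and Igfbp4 each ended when CC 1, CC 3, CC 4 or RC 1 was left out, with adjusted p up to 0.065 for Tap1 and up to 0.146 for Srebf1. They also ended without CC 2, except that of Hmgcs1, and without RC 2, except that of Tap1. Further losses came without DC 2 (Xbp1, Srebf1, Slc40a1 and Igfbp4), RC 3 (Xbp1, Vcl, Srebf1 and Slc40a1) and RC 4 (Srebf1, Slc40a1 and Ttr). Cltrn, Mt1, Mt2, Selenop, Ppargc1a and Jun passed with each array left out.

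The rows that differed between DC and CC were sorted by what the other comparisons called. The class names compare the final levels alone, since the level of RC cultures before the return was not analysed here. Of the 2360 rows 683 had returned, in that they differed between RC and DC in the opposite direction and not between RC and CC, and 298 of these had been higher in DC. The lack of a call between RC and CC does not place a row at the CC level. Ak4 and Bnip3 are in this class with RC above CC by 0.95 and 0.94 (limma adjusted p = 0.13 and 0.053). Second, dimmer probe sets of these genes lay above CC by less, 0.30 and 0.67 (limma adjusted p = 0.33 and 0.25). In the simulated data 36% of changes of 0.5 were recovered for RC against CC. Another 43 had partly returned, differing from both, among them Ccdc80, Tacr3, Agt, Mt1, Mt2, Hmgcs1 and Sv2b. In 167 rows the difference from CC was kept in RC with none called between RC and DC, 15 of them higher in DC. Cav1, Cltrn, Ephx1, Serping1 and Cpeb1 were in this class. The RC against CC calls behind the classes of Ccdc80, Hmgcs1, Serping1 and Cpeb1 ended without CC 1, CC 3, CC 4, RC 1 or RC 2 (adjusted p up to 0.121, 0.0881, 0.157 and 0.11). The remaining 1467 were mostly (1462) called in DC against CC alone, and in 1420 of those RC lay between CC and DC. Returned rows numbered 1605 without RC 3, 433 without RC 1, 436 without DC 2 and 450 without RC 4. Kept rows numbered 34, 49 and 95 without RC 1, RC 2 and RC 4 and 53, 64, 36 and 35 without CC 1, CC 2, CC 3 and CC 4. Rows were also chosen on 2 CC and 2 DC arrays and measured on the other 2 of each. A median of 25.7% of the DC difference was left in RC for rows higher in DC (17.1% to 35.9% over 6 choices) and 31.4% for rows lower in DC (27.3% to 39.9%). The RC level was the mean of all 4 RC arrays in every choice, RC 3 included. Over the rows that best separate DC from CC, RC 3 lay 39.8% of the way to DC, against 23.7% to 28.0% for the other RC arrays.

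**Figure D4:**
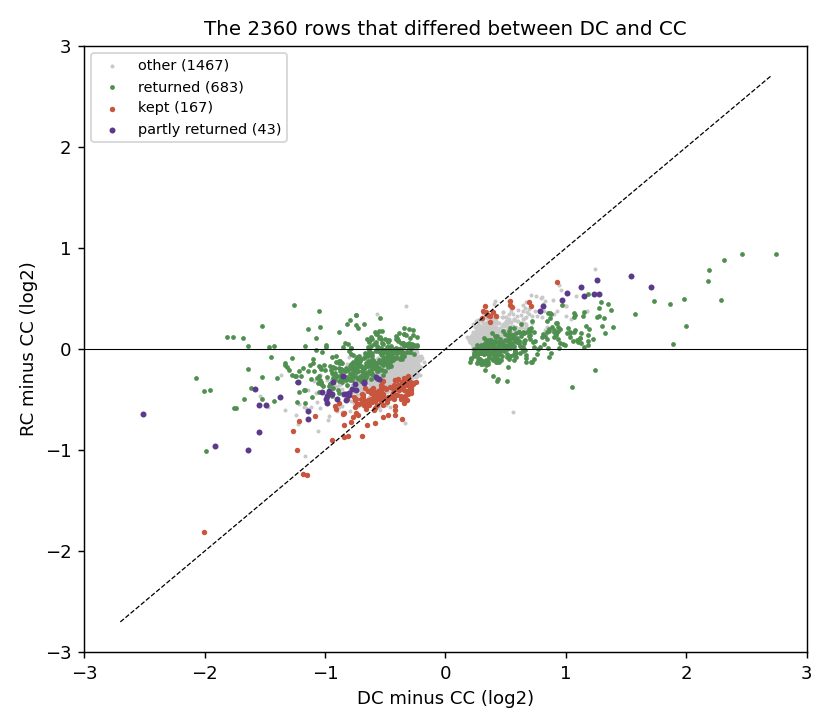
Log2 difference of RC from CC (vertical axis) against that of DC from CC (horizontal axis) for the 2360 rows that differed between DC and CC, coloured by class; rows on the horizontal line are back at the CC level and rows on the dashed diagonal remain at the DC level. Most of the 683 returned rows lie nearer to the horizontal line than to the diagonal, and the 167 kept rows lie near the diagonal, mostly in the lower left.

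Of the 283 rows that differed between RC and CC, 211 differed between DC and CC in the same direction (185 lower and 26 higher in both), 4 in the opposite direction and 68 not at all. Both comparisons share the CC arrays. Independent lists of these sizes would share 10.4 lower and 0.995 higher rows, against the 185 and 26 seen. Fits with 2 CC arrays per comparison called fewer rows, a median of 17.5 lower and 5 higher for RC. With different CC arrays in the comparisons, a median of 15.5 of the lower rows (11 to 37) and 2 of the higher (1 to 5) were shared, where independent lists would share 0.355 and 0.0481. With the same 2 CC arrays in both, the medians were 15.5 (11 to 43) and 2 (1 to 9). Across all rows, which are not independent replicates, the correlation of both differences was 0.646, against a mean of 0.424 (-0.357 to 0.952) in 100 simulations of unchanged groups, and their covariance 0.0221, against 0.00726 (-0.00777 to 0.0477). Both values lay within the simulated range. With different CC arrays in the comparisons the correlation was 0.466 (0.206 to 0.554) and the covariance 0.0178 (0.00886 to 0.0204), and with the same 2 they were 0.670 (0.593 to 0.777) and 0.0252 (0.0200 to 0.0421).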

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

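The tests of RC 3, of the narrow arrays and without the unnamed rows were chosen only after the result was seen. In each group of 4 arrays the highest and the lowest value were compared with the nearest other value, over the named genes and over measures of the arrays. Of 357 such groups over named genes 15 had a value far from the others, and chance alone gives about 17.9. Most values were on DC arrays. DC 4 was apart for Atf5 (9.02, against 9.26 to 9.29 on the other DC arrays), Ier3 (8.64, against 9.22 to 9.25), Lss (10.46, against 10.80 to 10.87) and Dll1 (8.30, against 8.01 to 8.06). DC 1 was apart for Ccdc80 (8.52, against 7.92 to 7.94) and Creld2 (12.32, against 11.61 to 11.73), DC 2 for Calb1 (7.28, against 7.59 to 7.63), and DC 3 for Dcx (11.59, against 11.73 to 11.76) and Lifr (9.64, against 9.44 to 9.45). In CC, Cav1 was low on CC 2 (9.11, against 9.23 to 9.24) and Dll1 high on CC 4 (7.83, against 7.62 to 7.64). In RC, Fasn was high (11.59, against 11.46 to 11.47) and Id1 low (9.67, against 9.84 to 9.86) on RC 2, Socs2 was high on RC 3 (8.44, against 8.24 to 8.25) and Sv2b on RC 4 (10.72, against 10.51 to 10.54).

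RC 3 lay far from the other RC arrays in its mean correlation with them (0.976, against 0.989 to 0.990) and in its scores on the first principal component (47.1, against -25.6 to -14.0) and the second (26.0, against -6.79 to -3.89). Over all rows RC 3 correlated at 0.973 to 0.977 with the other RC arrays, which correlated at 0.995 to 0.997 among themselves. It correlated at 0.981 to 0.990 with the DC arrays and at 0.974 to 0.983 with the CC arrays. All rows thus place RC 3 nearer to DC than to its own group. The rows that separate DC from CC nevertheless argue against a DC or CC sample under the RC label. Over the 200 rows that best separate DC from CC, RC 3 was 39.8% of the way from CC to DC, while the other RC arrays were at 23.7% to 28.0%, the DC arrays, placed on rows chosen without them, at 78.9% to 109.1% and the CC arrays at -0.36% to 3.63%. It was thus 36.2 percentage points above the highest CC array, a test that replaced one on the rows called between RC and CC, where RC 3 kept 30.6% of the change and the other RC arrays 81.6% to 98.5%. A shared axis may account for part of its distance: over all rows its deviation from the other RC arrays correlated at 0.596 with the difference of DC 2 and DC 4 from DC 1 and DC 3, and at -0.02 and -0.11 with the other ways to halve the DC arrays. DC 2 and DC 4 were picked for a narrow spread, which RC 3 has too, so this correlation cannot tell whether the axis is technical. What gave these arrays their narrow spread stays open, and no biological explanation was tested.

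Of the rows called between RC and CC most were lower in RC, 84.8% of 283. The values of RC 3 may account for part of this excess of lower rows, since 62.1% were lower without RC 3 alone, against 85.4% without DC 2, 80.1% without DC 4 and 79.5% to 90.7% when any of the 9 other arrays was left out. Without all 3 arrays of narrow spread 58.8% were lower. Narrow spread in general and RC 3 by itself cannot be told apart here, because DC 2 and DC 4 are in neither group and enter only the estimate of the spread. The unnamed rows at the start of the numbering do not account for it, with 83.6% lower without them. With array weights 47.6% of 2818 rows were lower. The share was 76.0% with quantile normalization, 86.3% with brighter rows only and 93.3% of 359 rows with the arrays centred on the median. A lower level of many genes after the return, which the design names, stays open and was not tested apart from RC 3 and the spread.

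Other splits of the arrays into groups of the same sizes were tried. For DC against CC the real split alone, 1 of 35, gave as many as 2360 rows, and the highest other split gave 0. This share, the smallest that 35 splits allow, makes chance unlikely for that count but does not exclude it. The other splits mix CC and DC arrays, which widens the spread within their groups, so their 0 is not a count for unchanged arrays. RC against CC, with 1 of 35, 283 rows and at most 0 in another split, has the same limits. For RC against DC chance cannot be excluded: 3 of 35 splits gave as many as 936 rows and the highest gave 7241. That split set RC 3, DC 2, DC 3 and DC 4 against RC 1, RC 2, RC 4 and DC 1, which points to a structure of the samples. The third split, with 1079 rows, set RC 3, DC 1, DC 2 and DC 4 against RC 1, RC 2, RC 4 and DC 3, so both exchanged RC 3 with a single DC array and otherwise kept the real groups. Of the 34 other splits only these 2 called more than 10 rows, so called list members can be set against these alone. The real split called 19 hypoxia, 18 cholesterol and 6 fatty acid genes, against at most 2, 0 and 1 in another. The real split also called more than any other in the beta cell (7, at most 3 in another), progenitor (4 and 3), antioxidant (4 and 3) and respiratory chain (2 and 1) lists. It called as many as the highest other in the JAK-STAT and Tie2 (3), cell cycle (3) and kept-low (2) lists. Another split called more in the remaining lists except that of ATF4 (0 in all). The real split had 1 and another 7 in the chaperone, Hes, Hey and Notch, interferon, and epithelial and mesenchymal lists. These numbers were 4 and 7 for the serum response, 2 and 5 for other islet hormones, 1 and 2 for iron and for neuronal genes, 0 and 6 for exocrine and ductal markers, and 0 and 7 for fibroblast, endothelial and immune markers. The number of gene lists called by camera was reached by 13 of 35 splits for DC against CC (8 lists, highest other 11), by 20 of 35 for RC against DC (7 lists, highest other 11) and by 29 of 35 for RC against CC (3 lists, highest other 11), so chance cannot be excluded for these counts. List by list, the hypoxia, cholesterol and fatty acid lists had their smallest camera p under the real split for RC against DC (1 of 35 each). The other called lists there were matched by 2 (respiratory chain), 4 (cell cycle), 9 (beta cell) and 18 (chaperones) of 35 splits. For DC against CC as small a p came from 5 splits for hypoxia, 2 each for cholesterol and fatty acids, 4 for chaperones, 7 for the cell cycle, 8 for the serum response, 13 for fibroblast, endothelial and immune markers and 18 for the respiratory chain. For RC against CC it came from 3 each for hypoxia and chaperones and 7 for beta cell genes. For the class of returned rows 1 of 100 groupings of the 12 arrays, the real one, gave as many as 683, with 629 in the next. These groupings are a random sample of those possible, and returned rows are part of the RC against DC calls. The next count lay within the range from leaving out single arrays, 433 to 1605. Chance and the structure of the samples are therefore not excluded for this class.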

How the results depend on the processing

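The settings with the arrays of narrow spread left out, with the interquartile range as a covariate and without the unnamed rows were chosen only after the result was seen. Of 190 results for named genes 154 passed the threshold. Among results that passed in the main fit or in the setting, 0 reversed direction. Changes of direction in results that passed in neither were not counted. Of the 154, 124 also passed in every planned setting in which they were tested, other than the 2-fold minimum, the test against 1.2-fold and the leaving out of arrays. Dimmer rows were not tested in the setting with brighter rows only, and 120 results passed with each array left out. For the counts, the cause of a change was not tested, except that the 2-fold minimum and the test against 1.2-fold are stricter by construction.

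The rows called for DC against CC, RC against DC and RC against CC numbered 2360, 936 and 283. With array weights they numbered 4840, 6413 and 2818, with at least 2-fold 170, 76 and 6, and tested against 1.2-fold 474, 161 and 11. With only the groups compared in the fit RC against DC gave 462. RC against CC gave 439 with brighter rows only, 491 with rows of 1 gene symbol, 580 without the 3 arrays of narrow spread, 636 with the interquartile range as a covariate and 433 without the unnamed rows, and with the covariate RC against DC gave 1737. With each array left out the counts were 1549 (without DC 2) to 3718 (without RC 3), 522 (without RC 1) to 2892 (without RC 3) and 57 (without RC 1) to 352 (without DC 4).

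Of the classes of rows, 683 returned, 43 partly returned, 167 were kept and 1467 were other. With at least 2-fold these were 117, 20, 7 and 26. Partly returned and kept rows numbered 71 and 270 with brighter rows only, 69 and 257 without the unnamed rows, and 90 and 291 with the interquartile range as a covariate, where 1028 returned. Without the 3 arrays of narrow spread 917 were other. With each array left out the ranges were 433 to 1605 returned, 10 to 59 partly returned, 34 to 191 kept and 945 to 1932 other.

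Gene lists called by camera numbered 8, 7 and 3. With an estimated correlation they numbered 1, 2 and 0, and with fry RC against CC gave 0. With brighter genes only DC against CC gave 7, of which 6 were among the main 8. RC against CC gave 6 with quantile normalization, 5 with brighter genes only, 6 without the 3 arrays of narrow spread and 6 with the interquartile range as a covariate. With each array left out the ranges were 6 to 10, 7 to 10 and 3 to 7.

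The replicate numbers of the 3 conditions did not pair the arrays: 5 of 12 same-numbered pairs had a correlation of deviations over 0.1 (-0.358 to 0.473), and 2 arrays correlated best with their own number. With the replicate block, 1852, 689 and 68 rows were called, 12 rows partly returned, 36 were kept, and 8, 7 and 3 lists were called. Without detection calls, signal over background could not be set as a limit for dim rows.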

Other observations

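The BMP and ERK tests of this part were chosen after Id1, Id2, Id3, Dusp6 and Spry4 had been seen to be lower in DC. Beyond the comparisons of the report, 38 rows differed in RC from both other conditions in the same direction, and the genes in this paragraph were chosen after their values were seen. Besides Akr1c18, Opn3, Slc1a2 and Ppargc1a, the melanosomal glycoprotein gene Gpnmb read 7.98 in RC against 7.33 in CC and 7.42 in DC (adjusted p = 0.00042 and 0.00021), the neurotrophin receptor Ngfr 10.36 against 10.02 and 9.45 (adjusted p = 0.018 and 1.4e-05), and the laminin receptor subunit Itga7 8.92 against 8.49 and 8.16 (adjusted p = 0.018 and 9.3e-05). Lower in RC than in both were the sarcoplasmic calcium pump gene Atp2a3 (11.22 against 11.95 and 11.61; adjusted p = 0.0019 and 0.02), the insulin receptor related receptor Insrr (9.03 against 9.65 and 10.21; adjusted p = 0.031 and 0.00014), the peptide receptor Vipr1 (9.25 against 9.84 and 9.82; adjusted p = 0.013 and 0.0042) and the photoreceptor cadherin Cdhr1 (9.94 against 10.64 and 10.73; adjusted p = 0.033 and 0.0056). Of these differences from CC, those of Akr1c18, Opn3, Ngfr, Itga7, Insrr, Vipr1 and Cdhr1 did not pass without CC 3 or CC 4, nor without other single arrays (adjusted p up to 0.0661, 0.0878, 0.0791, 0.0742, 0.117, 0.0594 and 0.125). That of Atp2a3 from DC did not pass without DC 3, RC 1 or RC 2 (up to 0.0762).

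Several genes were near their low DC level in RC, and their level before the return was not analysed here. The tetraspanin Cd9 read 10.48 in CC, 9.67 in DC and 9.62 in RC, with a difference of RC from CC of -0.86 ± 0.10 (SE, n = 4 per group; limma adjusted p = 0.0032). The metalloprotease gene Adamts9 is represented by several rows, 3 of which were in this class, with differences of RC from CC of -0.81, -0.71 and -0.66, none of which passed without CC 1, CC 2, CC 3, CC 4 or RC 1 (adjusted p up to 0.0765, 0.103 and 0.0878).

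Id1, Id2 and Id3, targets of BMP and SMAD signalling, were lower in DC, and a hypothesis was that other BMP and SMAD target genes were lower as a list. Of 17 measured genes, listed before their values were looked at and with members of the earlier lists left out, 3 fell (Smad7, Grem1 and Bmper) and none rose. Camera with the preset correlation gave p = 0.459 (adjusted p = 0.459 over the 6 tests of both hypotheses) with a direction down, while the median change was 0.05. By the rule first written for this test, a median that was not negative counts against the hypothesis, and that rule was met. The rule applied here also asked that the median exceed its standard error, which it did not. By that stricter rule the list neither bears out nor excludes the hypothesis. Smad7 read 8.76 in CC, 8.29 in DC and 8.75 in RC (adjusted p = 0.0024 for DC against CC), Grem1 11.07, 10.39 and 11.32, and Bmper 9.02, 8.37 and 8.87. From DC to RC 4 of the 17 rose.

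Dusp6 and Spry4, feedback inhibitors of ERK signalling, were lower in DC, and a hypothesis was that other ERK feedback and target genes were lower too, listed in the same way. Of 14 measured genes 4 fell and none rose: Etv5 (9.79 in CC, 8.47 in DC and 9.61 in RC; log2 change -1.32 in DC), Etv4 (-0.83), Dusp5 (-0.64) and Spred2 (-0.43), which did not pass without CC 1 (adjusted p = 0.058). Camera with the preset correlation gave p = 0.000145 for DC against CC (adjusted p = 0.00043, and adjusted p = 0.015 with an estimated correlation), with a median of -0.32. From DC to RC 4 rose and none fell (adjusted p = 3.3e-05, and adjusted p = 0.0099 with an estimated correlation). Between RC and CC none passed (adjusted p = 0.31). Lower ERK activity in the serum-free medium at low oxygen remains a hypothesis, since transcripts were measured and not ERK itself. Serum, the supplements and oxygen were not varied separately. Lists called by camera also arose under other splits of the arrays, whereas the called members did not for DC against CC, where the highest other split called 0 rows. Those splits mix CC and DC arrays, so that 0 adds little weight to the called ERK members.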
